A study of Mus musculus with 5 samples.

How the data were processed

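Sorted Tregs from lymph nodes and adipose tissue of C57BL/6 mice were used for RNA extraction with Trizol and library construction from 3 ug of total RNA with an Illumina TruSeq kit, per the labels' protocols. Sequencing was on an Illumina HiSeq2000 instrument, in a single experiment, per the series design text. The gate used for sorting is not given in the sources used here. There were 5 libraries, 1 per group, grouped by title, tissue, age, genotype and the design text.

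The submitters' processing notes name Bowtie2 2.0.6, TopHat2 2.0.9 and the mm8 genome build. The read counter, annotation, strand setting and normalization are not given in the sources used here, so reads of overlapping genes, antisense genes, pseudogenes and near-identical copies may have been split in ways that cannot be checked. The authors deposited 3 tables, each of 2 libraries, with Ensembl gene IDs, a scaled read count per library (the signal used here), a log2 fold change, a p-value, a q-value and a mark. Both 4-month tables hold 49671 IDs and the same LN library, and the 10-month table holds 47069. From the values, 100% of the authors' nonzero scaled counts were whole multiples of 1 step per library, within 0.01 read, so the step is the worth of 1 read. It was 0.108 and 0.109 scaled counts for LN in its tables, 0.111 for lean adipose, 0.126 for obese adipose, 0.115 for Foxp3Cre and 0.196 for the library labelled Med23 KO. Scaled counts under 1 are listed as 0 in the deposited tables, so the smallest nonzero values stand for 6 to 10 reads. For this reason the values were not treated as raw counts and no count model was fitted. The authors' log2 fold changes differed from the log2 ratio of the listed values by at most 0.000192 where both were above 0. Where 1 was listed at 0, they were computed from the value under 1, with 0.5 in place of no reads. The authors' mark stands exactly where the absolute log2 fold change is above 1 and the q-value is under 0.005 (0 exceptions). Those q-values compare 2 libraries and not conditions, and no p-value is printed.

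The design fixed before the data were examined foresaw raw counts or normalized values. As the values were normalized, they were used as deposited, without TMM scaling. Gene symbols came from a GENCODE M21 name table. Where several IDs shared a symbol, the ID with more reads was kept. No coordinates are printed because the tables hold none. Ratios are log2((value + 1)/(value + 1)), which understates the ratio of low genes. A gene was measured if it had 1 or more in at least 1 of the 2 libraries, and counts of genes use a 2-fold size threshold on this scale. Folds printed for single genes are ratios of listed values without the pseudocount. Where 1 value was listed at 0, both values are given and no fold. The 95% counting interval of a fold is the exact Clopper-Pearson interval, conditional on the sum of both libraries' reads, from the reads recovered with the step. The design foresaw it for raw counts alone, and it was added after the data were seen. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only. Obese and lean adipose values were put on 1 scale through the LN library that both tables hold. Values across the 10-month and 4-month tables are given as CPM, counts scaled to the same total of listed reads, or side by side.

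With 1 library per group no test between conditions exists, and no replicate could be left out. Of 26 gene lists fixed before the data were examined, the median log2 ratio of measured members was placed as a percentile among 10000 random lists of the same size, matched in 20 bins of mean expression. This describes the libraries and is no test. The lists were the adipose Treg signature, core Treg, naive and lymphoid T cell, effector and checkpoint, helper T cell cytokines and regulators, lipid uptake and fatty acid metabolism, cholesterol synthesis, glycolysis, insulin and growth factor signalling, proliferation, interferon response, immediate early and NF-kB, apoptosis and survival, Mediator complex, heat shock, adipocyte, macrophage and dendritic cell, B cell, CD8 T and NK cell, fibroblast and mesothelial, endothelial, granulocyte and mast cell, erythroid, ribosomal proteins, oxidative phosphorylation and mitochondrial genome. Named genes were Med23, the 10 highest and the 10 lowest ratios among genes at 5 or more in the higher library (without predicted genes, small RNAs and antigen receptor segments), the 4 members of each list with the largest ratios either way, and Foxp3, Pparg, Il1rl1, Gata3, Klrg1, Ccr7 and Il10. One gene of this rule is not reported here. Xist, Ddx3y, Gapdh and Cdk2ap2 were singled out across all libraries after their values were seen.

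Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated data made from the real means and read totals, with 200 genes altered in each comparison. For the library labelled Med23 KO against Foxp3Cre (13549 genes), 88.0% of genes altered 3-fold and 100% of those altered 6-fold or 12-fold were called at 2-fold, and 4.70% of unaltered genes were called, 1 of them with a mean of 5 or more. For lean adipose against LN (13541 genes) these shares were 94.0%, 100% and 3.30%, with 0 unaltered calls at a mean of 5 or more. The 95% intervals held the true ratio for 96.0% of genes with an interval in both comparisons. The simulated reads held counting error only, as the intervals assume, so these shares leave out any spread between libraries. Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, a filter of 5, no filter, centring on the median, equal totals, a 4-fold threshold, 2-fold gene sets and, for obese against lean, the difference of the ratios to LN. Alternatives chosen after seeing the data were values under 1 taken from the authors' log2 fold changes, a mean of 100 or more, the 10-month Foxp3Cre library in place of the lean one, the Foxp3Cre library thinned to the depth of the library labelled Med23 KO, gene sets from obese adipose, and lists without members of the lists for other cell types. For further tests, 28 macrophage genes outside the fixed lists were chosen before their values were seen, and genes at least 4-fold higher in LN (20 CPM or more) than in the 10-month Foxp3Cre library were used to test for replacement by LN-like Tregs, with 1000 bootstrap draws.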

Results

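Regulatory T cells (Tregs) were sorted from lymph nodes or adipose tissue of C57BL/6 mice and their messenger RNA was sequenced, with 1 library in each of 5 groups. The lymph node (LN) library and 2 adipose libraries came from 4-month mice carrying the Cre recombinase in Foxp3, the gene of the lineage-defining Treg transcription factor (Foxp3Cre mice). One of these adipose libraries came from obese mice and has HFD, the usual short form of high-fat diet, in its title. The other is called lean here only because its labels name no obesity. The remaining adipose libraries came from 10-month mice, a Foxp3Cre library and a library labelled Med23 KO, from mice with floxed Med23 alleles and Foxp3Cre. Med23 encodes a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. The reads behind the listed values numbered 9694474 for LN, 8540594 for lean adipose, 7496496 for obese adipose, 9650769 for Foxp3Cre and 4595046 for the library labelled Med23 KO. Values are scaled read counts. No group had a replicate, so no difference below could be set against the spread between mice, and intervals in parentheses after a fold are 95% counting intervals that cover counting error only.

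Med23 (ENSMUSG00000019984) did not follow the knockout label. It had 13.9 scaled counts in the library labelled Med23 KO and 7.02 in the 10-month Foxp3Cre library, a 1.98-fold higher value (1.39 to 2.84). In CPM these were 15.45 and 6.32. In the 4-month libraries Med23 had 6.71 in LN, 44.6 in lean adipose and 31.1 in obese adipose Tregs. Counts over a whole gene do not show whether the floxed exons were lost, so they do not settle which genotype the library has. Every direction given for that library therefore rests on its label. Foxp3 was listed above 0 in all 5 libraries, at 55.1 in LN, 206 in lean adipose, 168 in obese adipose, 206 in Foxp3Cre and 139.5 in the library labelled Med23 KO.

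**Figure D1:**
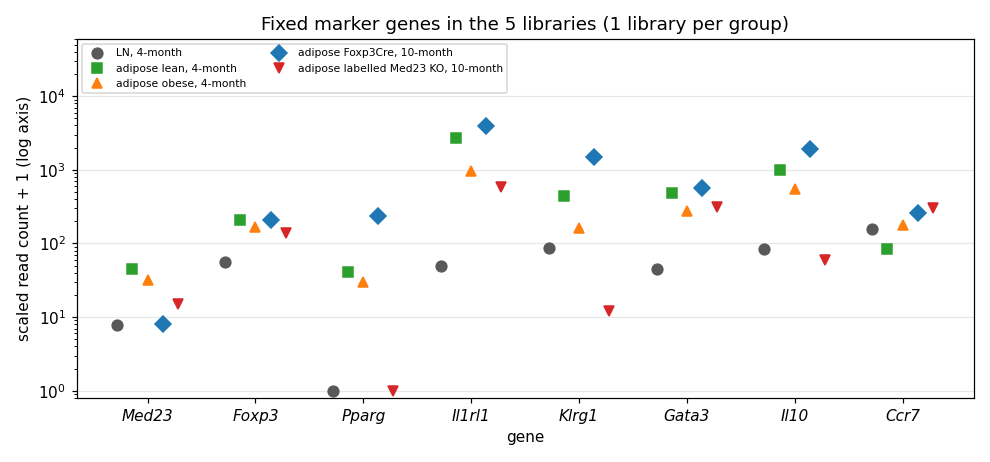
Scaled read count + 1 (log axis) of Med23 and 7 marker genes named in every comparison, with 1 point per library. Pparg is listed at 0 in the LN library and in the library labelled Med23 KO, and the 4-month and 10-month tables were normalized separately.

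The libraries also split in a way the groups do not name. Xist, the RNA of the inactive X chromosome in females, had 239 scaled counts in LN, 489 in Foxp3Cre and 541 in the library labelled Med23 KO, and the Y-linked gene Ddx3y was listed at 0 in these 3 libraries. In lean and obese adipose Tregs Xist had 0 and 3.36, and Ddx3y had 532 and 524. Gapdh, a glycolytic enzyme gene used by all cells, had 1028 in LN, 709 in Foxp3Cre and 492 in the library labelled Med23 KO but 1.002 in lean and 9.95 in obese adipose Tregs, and Cdk2ap2 had 1491, 694 and 286 against 0 in both 4-month adipose libraries. Of 3920 genes at 20 CPM or more (counts scaled to the same total of listed reads) in LN and both 10-month libraries, 27 were under 2 in both 4-month adipose libraries, and pseudogenes took 1.54% and 1.31% of reads in these against 0.469% in LN, 0.725% in Foxp3Cre and 1.02% in the library labelled Med23 KO. Lean or obese adipose against LN thus also differs in these sex markers and in genes near 0, and ratios without a value from the 10-month Foxp3Cre library below were not separated from this.

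Lean adipose against LN Tregs asked what distinguishes Tregs of fat from those of lymphoid tissue. Genes of the adipose Treg signature stood far above LN. Il1rl1, which encodes the IL-33 receptor ST2, had 2745 scaled counts in lean adipose against 48.8 in LN Tregs, 56.2-fold higher (51.2 to 61.8). Pparg, a nuclear receptor needed for adipose Tregs, had 39.99 and was listed at 0 in LN. Gata3 was 11.2-fold higher (10.1 to 12.4), Il10, the gene of an anti-inflammatory cytokine, 12.3-fold higher (11.4 to 13.2), Klrg1 5.03-fold higher (4.66 to 5.43) and Foxp3 3.73-fold higher (3.38 to 4.12).

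Of the 29 measured members of the adipose Treg signature, 28 were at least 2-fold higher in lean adipose than in LN Tregs and none at least 2-fold lower, with a median log2 ratio of 3.65, above all 10000 random lists matched on expression (percentile 100). Dgat1, an enzyme of triglyceride synthesis, was 233-fold higher (201 to 272), Ccr1 had 97.8 against 0, and Il5 had 86.7 against 0. Core Treg genes went both ways, with 7 of 20 higher and 6 lower. Plagl1 was 14.6-fold higher (12.5 to 17.0), Entpd1 6.50-fold lower (5.05 to 8.48), and Itgae and Gpr83, at 186 and 72.0 in LN, were listed at 0 in lean adipose. Of the naive and lymphoid T cell list, 8 of 20 members were lower and 1 higher (median -0.92, percentile 3.00). Ccr7, a chemokine receptor gene of lymphoid T cells, was 1.89-fold lower (1.72 to 2.06). Of the effector and checkpoint list, 9 of 20 were higher and 4 lower (percentile 90.0), and Pdcd1, the gene of the inhibitory receptor PD-1, was 44.6-fold higher (32.0 to 64.3), Ccr4 45.5-fold higher (28.6 to 77.3) and Itgav 19.3-fold higher (18.3 to 20.4).

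Genes of acute activation and of heat shock were also higher in lean adipose Tregs. Of the immediate early and NF-kB list, 15 of 26 were higher and 2 lower (median 1.39, percentile 100), with Ier3 103-fold higher (66.1 to 172), Fosl2 69.0-fold higher (57.8 to 83.0) and Nr4a1 34.8-fold higher (30.7 to 39.7). Of the heat shock list, 10 of 12 were higher and none lower (median 2.76, percentile 100). The chaperone gene Hspa1b had 1815 against 0, and Hsph1 was 79.3-fold higher (65.7 to 96.5). The cholesterol synthesis list had 12 of 20 higher and 3 lower (median 1.85, percentile 99.1). Its member Stard4, a sterol transfer gene and not a synthesis enzyme, had 69.1 against 0, while Msmo1 had 0 against 56.0. Of the lipid uptake and fatty acid list, 12 of 27 were higher and 6 lower (median 0.74, percentile 85.4). Without members of the lists for other cell types, 9 of 24 were higher and 6 lower (median 0.21, percentile 57.7). In the full list Plin2, which coats lipid droplets, and Cd36, a fatty acid transporter also on the adipocyte list, had 378 and 47.8 against 0, while Acaa2 was 44.7-fold lower (27.7 to 77.2). Irs2, an adaptor of the insulin receptor, had 450.0 against 0, in a list of insulin and growth factor signalling with 7 of 17 higher and 3 lower (percentile 91.6).

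Lower in lean adipose Tregs were genes of cell division, of the interferon response and of protein synthesis. Of 24 proliferation genes, 13 were lower and 4 higher (median -1.40, percentile 0.200), with the mitotic cyclin gene Ccnb2 at 0 against 120.3 in LN. Of 22 interferon response genes, 12 were lower and 6 higher (median -1.15, percentile 1.35), with Usp18 at 0 against 38.8. Ribosomal protein genes had 65 of 82 lower and 4 higher (median -1.30, percentile 0), and oxidative phosphorylation genes 32 of 77 lower and 4 higher (median -0.90, percentile 0.0950). Genes of the mitochondrial genome had 8 of 12 lower and 1 higher (median -1.22, percentile 1.20), and the glycolysis list went both ways, with 6 of 16 higher and 6 lower.

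Lean adipose and LN Tregs also differed in markers of other cell types. Of 19 macrophage and dendritic cell genes, 18 were higher in lean adipose (median 4.23, percentile 100), with the mannose receptor gene Mrc1 at 175 and Cd14 at 131 against 0. Of 12 fibroblast and mesothelial genes, 11 were higher (median 4.47, percentile 100), led by the proteoglycan gene Dcn at 752 against 0. All 4 measured erythroid genes were higher, with Hba-a1 at 295 against 0. All 3 measured adipocyte genes (Cd36, Acsl1 and Fabp4) were higher too, but each is also on the lipid uptake and fatty acid list. The erythroid and adipocyte lists summed to 0 in LN, so every measured member had to count as higher. The adipocyte genes Adipoq and Plin1 had no value above 0 in lean adipose or LN. The B cell list had 6 of 10 lower and 3 higher (percentile 7.20), and the list for CD8 T and NK cells 3 of 7 lower and 2 higher (percentile 34.0). Among the 10 highest and the 10 lowest genes by the naming rule were also Ccl7 (1003), Retnla (722), Cxcl1 (539) and Wfdc17 (384), each listed at 0 in LN, and Lta (286), Capn3 (144) and Ranbp1 (385), each listed at 0 in lean adipose. Ranbp1 is among the 27 genes near 0 in both 4-month adipose libraries.

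In all, 5098 of 13541 measured genes were at least 2-fold higher in lean adipose and 4344 at least 2-fold lower, but among the 2014 genes with a mean of 100 or more 430.0 were higher and 612 lower. The authors' deposited table marks 6510 genes as differing between these libraries, not conditions, 3562 of them higher in adipose. With the 10-month Foxp3Cre adipose library, which shares Xist, no Ddx3y and Gapdh with LN, in place of the lean one, 4529 of 13187 genes were higher and 3926 lower, in CPM because the tables were scaled separately, and the age then differs. In that comparison the adipose Treg signature had 27 of 29 members higher (median 4.44), the immediate early list 16 of 26 higher (median 1.63) and ribosomal proteins 66 of 78 lower (median -1.50), but the proliferation list had 9 of 24 higher and 2 lower (median 0.27), the heat shock list 6 of 12 higher and 2 lower (median 0.94, percentile 95.3), the mitochondrial genome 2 of 12 lower (percentile 13.3), the naive and lymphoid list 8 of 19 lower and 2 higher (percentile 12.2) and the fibroblast and mesothelial list 2 of 4 higher and 1 lower. Macrophage and dendritic cell genes were higher in it too, 13 of 16 with 1 lower (median 2.74, percentile 100). All 4 measured erythroid genes were higher in it (median 8.26), which was fixed by their values of 0 in LN. Ccr7 was 1.56-fold higher in it (1.45 to 1.66), not lower. Cholesterol synthesis had 14 of 19 higher and 3 lower there (percentile 99.99), and effector and checkpoint 11 of 20 higher and 2 lower (percentile 100). Oxidative phosphorylation had 54 of 76 lower and 4 higher (percentile 0), while insulin and growth factor signalling had 6 of 17 higher and 6 lower.

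Obese adipose against LN Tregs showed the adipose Treg markers on the same side as in lean adipose, with smaller folds. Il1rl1 was 19.6-fold higher (17.8 to 21.6), Gata3 6.25-fold higher (5.62 to 6.97), Il10 6.67-fold higher (6.18 to 7.22), Klrg1 1.83-fold higher (1.68 to 2.01) and Foxp3 3.05-fold higher (2.75 to 3.38). Pparg had 29.6 scaled counts and was listed at 0 in LN. Ccr7 was 1.14-fold higher (1.06 to 1.23).

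Of the 29 measured members of the adipose Treg signature, 25 were at least 2-fold higher in obese adipose and none at least 2-fold lower (median 3.00, percentile 100), among them Dgat1, 119-fold higher (102 to 138), and Cd36, with 341 against 0. The effector and checkpoint list had 10 of 19 higher and 1 lower (median 1.11, percentile 99.96), with Pdcd1 50.7-fold higher (36.3 to 73.0). The immediate early and NF-kB list had 16 of 26 higher and 2 lower (median 1.40, percentile 100), with Rel, an NF-kB subunit gene, 16.7-fold higher (15.5 to 18.2). Lipid uptake and fatty acid genes had 17 of 29 higher and 2 lower (median 1.21, percentile 99.0), with Plin2 at 472 and the fatty acid binding protein gene Fabp4 at 277 against 0. Ribosomal protein genes had 70 of 81 lower and 3 higher (median -1.45, percentile 0), and oxidative phosphorylation genes 36 of 78 lower and 3 higher (median -0.96). Of 25 proliferation genes, 11 were lower and 6 higher (median -0.75, percentile 1.71). Core Treg genes had 6 of 20 higher and 4 lower, with a median of 0.42 that became -0.03 when ratios were centred on the median of all genes. Mediator complex genes had 12 of 30 higher and 6 lower (median 0.80, percentile 98.5), or 9 higher and 10 lower when centred (median 0.36), with Med17 18.6-fold higher (11.1 to 33.8), where lean adipose had 8 of 28 higher and 11 lower (percentile 56.8).

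Macrophage and dendritic cell genes had 21 of 22 higher in obese adipose than in LN (median 6.19, percentile 100), with the complement genes C1qb at 739 and C1qc at 546 against 0. Further genes among the 10 highest were the chemokine genes Ccl8 (1079), Ccl7 (926) and Pf4 (915), each listed at 0 in LN. All 5 erythroid genes and all 9 measured adipocyte genes were higher. Both lists summed to 0 in LN, so every measured member had to count as higher. The list for CD8 T and NK cells had 7 of 12 higher and 2 lower (percentile 92.5). The adipocyte genes with the largest ratios, Cd36, Fabp4, Acsl1 and Lipe, are also on the lipid uptake and fatty acid list. The B cell list had 7 of 11 lower and 3 higher (median -1.28, percentile 0.78), and fibroblast and mesothelial genes 6 of 8 higher and 2 lower (percentile 58.1). In all, 6144 of 14713 measured genes were at least 2-fold higher and 3484 at least 2-fold lower, but among the 2055 genes with a mean of 100 or more 391 were higher and 612 lower. Scaling to equal totals gave 6456 higher and 3120 lower, and centring on the median log2 ratio of 0.44, which balances the sides by construction, gave 4612 and 4615. The authors' deposited table marks 5293 genes as differing between these libraries, not conditions. No obese library shares the sex markers and Gapdh level of LN, so no value without that split could be had.

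Obese against lean adipose Tregs asked how obesity of the host, together with its diet, goes with the Treg transcriptome of fat. The 2 libraries share the Y-linked reads and the low Gapdh. The adipose Treg markers were lower in the obese library. Il1rl1 was 2.86-fold lower (2.79 to 2.94), Klrg1 2.74-fold lower (2.57 to 2.92), Il10 1.84-fold lower (1.78 to 1.91), Gata3 1.79-fold lower (1.70 to 1.89) and Pparg 1.36-fold lower (1.15 to 1.61). Foxp3 was 1.22-fold lower (1.14 to 1.31), while Ccr7 was 2.15-fold higher (1.96 to 2.35).

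Of the 30 measured members of the adipose Treg signature, 11 were at least 2-fold lower in obese than in lean adipose Tregs and 4 at least 2-fold higher (median -0.84, percentile 0). Irf4, a transcription factor of effector Tregs, was 5.46-fold lower (4.91 to 6.08) and Homer2 had 0 against 14.7, while Cd36 was 7.07-fold higher (6.38 to 7.85) and Hpgd had 25.3 against 0. The naive and lymphoid T cell list had 9 of 20 higher and 1 lower (median 0.90, percentile 99.96). Core Treg genes had 6 of 20 higher and 2 lower (median 0.06, percentile 81.0), with the IL-2 receptor gene Il2ra 5.05-fold lower (4.83 to 5.29) and Entpd1 8.90-fold higher (6.93 to 11.6). Of 23 interferon response genes, 14 were higher and 1 lower (median 1.48, percentile 99.99), with the antiviral genes Rsad2 at 141 against 0 and Ifit1 13.96-fold higher (10.6 to 18.8). Heat shock genes had 8 of 12 lower and none higher (median -1.26, percentile 0), with Hspb1 18.6-fold lower (13.6 to 26.0). Proliferation genes had 11 of 23 higher and 2 lower (percentile 96.3), with Ccnb2 at 27.1 against 0. Lipid uptake and fatty acid genes had 12 of 30 higher and 5 lower (percentile 75.5), with lipoprotein lipase, Lpl, 15.7-fold higher (12.7 to 19.6) and Fabp4 21.01-fold higher (17.4 to 25.5). Cd36 and Fabp4 are also on the adipocyte list, and RNA of co-sorted cells was not separated from any of these lists.

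Beside these, markers of other cell types differed between the obese and lean libraries. All 22 macrophage and dendritic cell genes were higher in the obese library (median 2.32, percentile 100), with C1qb 9.58-fold higher (8.85 to 10.4) and C1qc 18.9-fold higher (16.7 to 21.5). Fibroblast and mesothelial genes had 11 of 12 lower (median -3.77, percentile 0), with Dcn 97.6-fold lower (76.0 to 127). The list for CD8 T and NK cells had 8 of 11 higher and 1 lower (median 3.24, percentile 99.8), with Gzmk at 24.8 and Cd8b1 at 13.4 against 0. Adipocyte genes had 8 of 9 higher (percentile 99.97, but 79.8 with a pseudocount of 0.1). Several of these were near the floor, such as Adipoq at 1.74 and Cidea at 4.73 against 0 in lean adipose. Among the 10 highest and 10 lowest genes were Ly86 (155), Tmem176b (119), Clec4a3 (93.7), Ckap5 (70.9), Tfam (67.4) and Igsf6 (66.4), each listed at 0 in lean adipose, and Ptx3 (105), Tm4sf1 (68.3) and Nid1 (63.5), each listed at 0 in obese adipose, with Sult1e1 112-fold lower (69.8 to 193). Ckap5 and Tfam had 93.7 and 116 in LN and 50.8 and 54.6 in the 10-month Foxp3Cre library, so lean adipose was the library without them. In all, 4809 of 14636 measured genes were at least 2-fold higher in the obese library and 2795 at least 2-fold lower. Among the 1941 genes with a mean of 100 or more, 106 were higher and 90 lower.

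**Figure D2:**
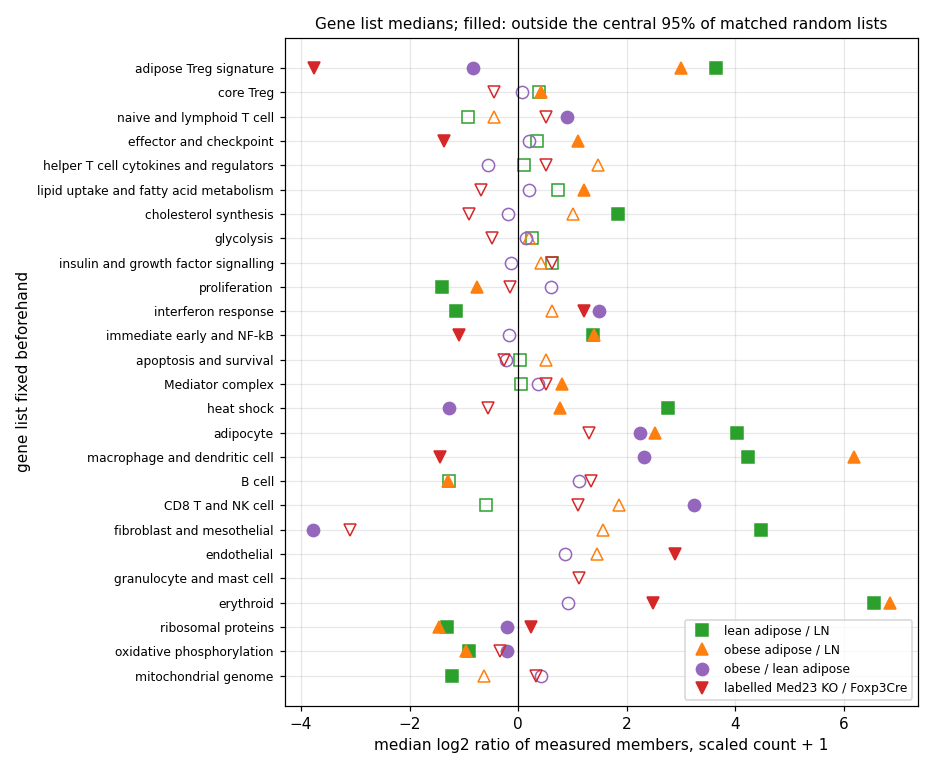
Median log2 ratio (scaled count + 1) of the measured members of each gene list, with 1 symbol per comparison of 2 libraries. Filled symbols lie outside the central 95% of 10000 random lists matched on expression, as the adipose Treg signature does in each comparison, from 3.65 for lean adipose over LN to -3.76 for the library labelled Med23 KO over Foxp3Cre.

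The 10-month comparison asked which genes of adipose Tregs depend on Med23. The library labelled Med23 KO had far less RNA of the adipose Treg markers than the Foxp3Cre library, although Med23 itself was not lower in it. Pparg had 235 scaled counts in the Foxp3Cre library and was listed at 0 in the library labelled Med23 KO. Klrg1 was 138-fold lower (106 to 183), Il10 32.8-fold lower (29.3 to 36.9) and Il1rl1 6.63-fold lower (6.39 to 6.89). Gata3 was 1.80-fold lower (1.70 to 1.90) and Foxp3 1.47-fold lower (1.35 to 1.61), while Ccr7 was 1.18-fold higher (1.10 to 1.26).

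Of the 29 measured members of the adipose Treg signature, 23 were at least 2-fold lower in the library labelled Med23 KO and 1 at least 2-fold higher (median -3.76, percentile 0). The chemokine gene Cxcl2 was 125-fold lower (110 to 143), and the chemokine receptor gene Ccr1 had 0 against 514. In the same comparison 13 of 17 macrophage and dendritic cell genes were lower and 1 higher, and RNA of co-sorted cells was not separated from the signature. The effector and checkpoint list had 12 of 20 lower and 1 higher (median -1.37, percentile 0), with Anxa2 14.9-fold lower (12.4 to 18.0) and the chemokine receptor gene Ccr8 5.97-fold lower (5.47 to 6.52). The immediate early and NF-kB list had 14 of 26 lower and 1 higher (median -1.08, percentile 0.01), with Atf3 7.27-fold lower (6.63 to 7.99), Ier3 at 0 against 235 and Egr1 at 0 against 142. Core Treg genes had 6 of 20 lower and 5 higher (percentile 11.6), among them Capg, 31.6-fold lower (23.2 to 44.1), Il2ra, 5.10-fold lower (4.84 to 5.38), and Tnfrsf4, 3.96-fold lower (3.86 to 4.07). Cholesterol synthesis genes had 9 of 19 lower and 2 higher (median -0.90, percentile 2.87), with Sc5d at 0 against 201 and Hmgcs1 at 0 against 42.0. Lipid uptake and fatty acid genes had 12 of 26 lower and 8 higher (percentile 7.75), with Plin2 at 1.17 against 587, 500-fold lower (230 to 1363). Glycolysis genes had 4 of 16 lower and 3 higher (percentile 10.3), with Aldoa 6.24-fold lower (5.58 to 7.003).

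Higher in the library labelled Med23 KO were interferon response genes and single genes of helper and naive T cells. Ifng, the gene of interferon gamma, had 95.1 against 0, but 138 in LN, 112 in lean and 128 in obese adipose, so Foxp3Cre was the library without it. Its regulator Tbx21 was 5.48-fold higher (3.52 to 8.78), within a list of helper T cell cytokines and regulators with 3 of 9 higher and 3 lower (percentile 74.3). Csf2 and Ccr6 of this list were lower, with 0 against 45.9 and 0 against 14.8. Of 23 interferon response genes, 13 were higher and 5 lower (median 1.21, percentile 99.7), with Usp18 21.5-fold higher (12.5 to 40.1) and Ifit1 18.8-fold higher (10.7 to 36.2), while Mx1 had 0 against 18.6. Here too Foxp3Cre was low, with 10 of 21 interferon response genes lower than in LN and 4 higher in CPM (median -0.99, percentile 2.47), and Usp18 and Ifit1 had 1.61 and 1.495 in it against 38.8 and 21.7 in LN. The naive and lymphoid list had 7 of 18 higher and 4 lower (median 0.51, percentile 97.3), but a median of 0.24 at percentile 85.9 over the 17 members left by a filter of 5, with the transcription factor genes Tcf7 7.75-fold higher (6.16 to 9.85) and Bach2 5.72-fold higher (4.50 to 7.33) and Klf2 3.56-fold lower (3.10 to 4.10). Other Mediator complex genes had 10 of 28 higher and 2 lower (percentile 96.6), with Med12 5.16-fold higher (3.88 to 6.92) and the Mediator kinase gene Cdk8 2.75-fold higher (2.34 to 3.23). Of 17 genes of insulin and growth factor signalling, 5 were higher and 3 lower (percentile 95.1), with Igf1r 10.1-fold higher (5.42 to 20.4). Ribosomal protein genes were within 2-fold for 73 of 78 members, with a median of 0.24 above most matched random lists (percentile 99.99), all 12 genes of the mitochondrial genome were within 2-fold (percentile 93.7), and oxidative phosphorylation genes had 19 of 75 lower and 3 higher (percentile 4.95). Proliferation genes had 9 of 25 lower and 6 higher (percentile 41.4), apoptosis and survival genes 7 of 19 lower and 2 higher (percentile 35.6), and heat shock genes 4 of 12 lower and none higher (percentile 17.3).

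Markers of other cells differed as well. Of 17 macrophage and dendritic cell genes, 13 were lower in the library labelled Med23 KO and 1 higher (median -1.43, percentile 1.93), with the lysozyme gene Lyz2 11.05-fold lower (9.71 to 12.6). All 5 erythroid genes were higher (median 2.49, percentile 100), with the haemoglobin gene Hbb-bs 6.87-fold higher (6.66 to 7.09). All 4 measured fibroblast and mesothelial genes were lower (percentile 3.23), B cell genes had 5 of 8 higher and 3 lower (median 1.34, but -1.57 over the 5 members left by a filter of 5, and summed scaled counts of 407 against 1165), CD8 T and NK cell genes 4 of 8 higher and 2 lower (percentile 94.0), with Cd8b1 21.3-fold higher (13.8 to 34.6) and Cd8a at 0 against 7.82, adipocyte genes 3 of 5 higher and 1 lower, endothelial genes 2 of 3 higher, and granulocyte and mast cell genes 2 of 3 higher and 1 lower. Among the 10 lowest genes were also Anxa1, 617-fold lower (395 to 1024), Cxcl3 (1381), Sertad1 (247) and Cxcl5 (244), the last 3 listed at 0 in the library labelled Med23 KO. Among the 10 highest were Nek8 (81.6), Zfp808 (79.8), Lax1 (74.2), Rnf128 (68.5), Rras2 (66.1) and Tcrg-C2 (64.8), each listed at 0 in Foxp3Cre. In all, 3877 of 13549 measured genes were at least 2-fold higher and 4730 at least 2-fold lower, and scaled to equal totals 4501 were higher and 4295 lower. The authors' deposited table marks 5113 genes as differing between these libraries, not conditions, 2567 of them higher in the library labelled Med23 KO.

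**Figure D3:**
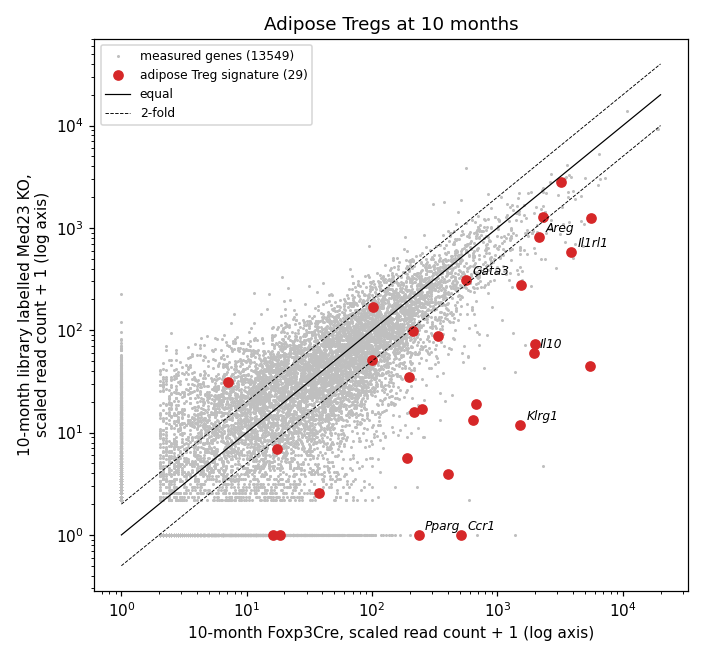
Scaled read count + 1 of each measured gene in the library labelled Med23 KO against the 10-month Foxp3Cre library (both log axes), with the 29 members of the adipose Treg signature in red. Of these, 23 lie below the lower dashed line of a 2-fold difference and 1 lies above the upper one, and genes listed at 0 lie at 1.

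The broader set of adipose genes did not share the size of the signature's difference. Of the 3092 genes at least 4-fold higher in lean adipose than in LN Tregs, 2047 were measured at 10 months. Their median log2 ratio in the library labelled Med23 KO over Foxp3Cre was -0.25, against -0.15 for matched random lists (percentile 1.63). Sets at least 2-fold higher gave -0.14 at percentile 51.9, a filter of 5 gave percentile 16.9, a pseudocount of 0.1 gave 15.6 and leaving out members of the lists for other cell types gave 4.56, while sets from the obese library gave -0.28 at percentile 0.645, so the low percentile held in some of these settings only. The 1810 measured genes of the set at least 4-fold lower in lean adipose had a median of -0.54 (percentile 0), also below random lists.

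Against the shared LN library, the log2 ratios of lean and obese adipose Tregs had a Pearson r of 0.810 across 12590 genes, which are not independent replicates. Unchanged libraries simulated with a shared LN library gave 0.498, a value that holds counting error and no spread between libraries. The covariance was 4.04 against a simulated 0.0294. Of the 4147 genes higher in lean and 4021 higher in obese adipose among these, 3359 were higher in both, where independent lists, which leave out the shared LN library, would share 1324 and the unchanged libraries shared 85.6. For lower genes the lists held 4344 and 3484 and shared 2675, where independent lists would share 1202 and the unchanged libraries shared 37.04. Part of the excess may come from the 1 LN library, which could not be divided.

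The 10-month and 4-month lean Foxp3Cre adipose libraries stand in tables normalized separately and differ in the sex markers and Gapdh, so their values are only set side by side. Pparg had 235 at 10 months and 39.99 at 4 months, Klrg1 had 1516 and 435, Il1rl1 had 3882 and 2745, Il10 had 1938 and 1007, Gata3 had 561 and 486, and Foxp3 had 206 in both. Ccr7 had 254 at 10 months and 82.0 at 4 months.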

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

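The tests in this part were chosen after the patterns were seen, and only for the thinning of the Foxp3Cre library and the further macrophage genes was the bound written before the result of the test, while the filter and pseudocount settings were fixed beforehand.

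Lean and obese adipose Tregs differed in opposite directions from the same LN library in 270 genes, of which 184 were at least 2-fold lower in lean and at least 2-fold higher in obese adipose. A filter of 5 gave 105 such genes, 61 of them higher in obese adipose, and a pseudocount of 0.1 gave 331, of which 225. The interferon response list had a median log2 ratio to LN of -1.15 in lean and 0.62 in obese adipose, a difference of 1.77 between medians of 22 and 24 measured members. The list for CD8 T and NK cells had -0.60 and 1.86, a difference of 2.46 between medians of only 7 and 12 members, which are not the same genes. Obese over lean adipose directly, the medians were 1.48 over 23 members and 3.24 over 11. With 1 library per group, these differences between lean and obese adipose were not tested.

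The adipose Treg signature was far above LN in the 4-month adipose libraries, which also differ from LN in sex markers and in genes such as Gapdh. Some genes may have been counted differently in these libraries, since 13 of the 27 genes near 0 in both of them, but not in the other 3 libraries, lay within 200 kb of another such gene, where random sets of as many genes had a median of 0 and at most 6. For the signature itself this explanation and the sex of the mice are argued against by the 10-month Foxp3Cre library, which shares the Xist and Gapdh reads of LN. In it the signature's median log2 ratio to LN was 4.441, with 27 of 29 members at least 2-fold higher. The ribosomal protein, oxidative phosphorylation, immediate early and NF-kB, and cholesterol synthesis lists also kept their direction against LN in it. Their medians were -1.50, -1.41, 1.63 and 2.18, which argues against the sex of the mice for them too, although no bound was written for these lists. Different counting remains open for them, since the 10-month table holds 47069 IDs and the 4-month tables hold 49671. All these ratios, the signature's included, also use the 1 LN library. For other lists, such as proliferation and fibroblast genes, batch, sex and tissue remain open, and tissue, which the design names, was not tested apart from them.

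The adipose Treg signature was lower in the library labelled Med23 KO. A lower number of reads alone is argued against, since thinning the Foxp3Cre library to the depth of that library left the list median at -3.747. Thinning keeps the expected ratio of genes with many reads, so it covers the number of reads only, and loss of RNA before sequencing was not tested. Replacement of adipose Tregs by Tregs like those of LN is argued against as the whole cause by the 622 genes at least 4-fold higher in LN than in Foxp3Cre. A mix that lowers the signature by its median would raise them by a median log2 ratio of 2.5003. Theirs was 0.6143 (bootstrap interval 0.45 to 0.81). They were picked for low values in Foxp3Cre, the lower side of this ratio, so part of their rise may come from the picking. Replacement of part of the cells remains open. Of the 622 genes, 259 were at least 2-fold higher and 146 lower, where 3877 of all 13549 measured genes were higher and 4730 lower. Exchanged labels remain open. Med23 was 1.98-fold higher (1.39 to 2.84) in the library labelled Med23 KO, an interval that includes the 2-fold bound set with this value in view. In CPM it had 15.45 against 6.32. Med23 also ranged from 6.71 to 44.6 in the 4-month libraries, and gene counts do not show the floxed exons, so it does not settle the labels. The signature stood above LN in lean, obese and Foxp3Cre adipose (28, 25 and 27 of 29 members higher). This goes with the labels as given, but age and sex markers differ. Log2 values across 9189 genes, which are not independent, correlated better with lean, obese and LN Tregs for Foxp3Cre (r 0.632, 0.713 and 0.682) than for the library labelled Med23 KO (0.497, 0.567 and 0.542), the deeper library being the closer in each. The genotype named by the design therefore also remains open as a cause and was not tested.

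Macrophage and dendritic cell genes were higher in the obese than in the lean adipose library, in all 22 measured members. More myeloid cells in the obese sort remain open, since 19 of 26 measured genes of a further macrophage list were at least 2-fold higher (median 2.17, percentile 100) and 1 lower, short of the more than 75% set beforehand. A sort on Treg markers would remove such cells, but the gate is not given. A lower Treg purity that raises all other cell types alike is argued against by the fibroblast and mesothelial list, whose median was -3.774. Obesity, which the design names, the diet in the title and a difference between single sorts cannot be separated with 1 library each. No test was run on that.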

How the results depend on the processing

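No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out. Settings chosen after seeing the data are those with a mean of 100 or more, values under 1 from the authors' log2 fold changes, thinning, the 10-month library in place of the lean one, obese gene sets and shortened lists. Of 122 recomputed counts and summary values, 101 stayed within 1.5 times the reported count or inside its interval. A 4-fold threshold, stricter by construction, left 3092 genes higher and 2378 lower for lean adipose against LN, 3189 and 1349 for obese adipose against LN, 2277 and 1109 for obese against lean, and 1874 and 2648 for the library labelled Med23 KO. A mean of 100 or more, which tests fewer genes, left 430.0 and 612, 391 and 612, 106 and 90.0, and 221 and 407 in the same order. The excess of higher genes became an excess of lower ones in both comparisons with LN under this setting, and the cause was not tested. A filter of 5 left 3750 genes higher in obese adipose than in LN and 2728 higher in obese than in lean adipose, since it removes low genes. The Pearson r of lean and obese ratios was 0.835 with a filter of 5 and 0.819 with a pseudocount of 0.1, and a filter of 5 left 105 genes in opposite directions. Of 397 list medians, 373 stayed inside their bootstrap interval or shifted by less than 0.1, 23 moved and 1 of those with a median of 1 or more turned, while centring also changed the sign of 9 medians of at most 0.43. The 100 medians of shortened lists all stayed, but most lists hold no member to leave out, so most of these could not move. The B cell list in the library labelled Med23 KO had a median of 1.34 over 8 members, and -1.57 with a filter of 5, which left 5 members. Of 3630 values for named genes, 410 moved, 260 of them with a pseudocount of 0.1. Filters only drop genes, so the 458, 486 and 152 values under a filter of 5, no filter and a mean of 100 or more could not move. None of the values at least 2-fold apart turned, but a pseudocount cannot change a sign, and centring or equal totals shift ratios too little to do so. Centring moved all log2 ratios by the median, 0.14 for lean and 0.44 for obese adipose against LN, 0.15 for obese against lean and -0.15 for the library labelled Med23 KO. Depth limits low genes, because a listed 0 can stand for up to 9 reads.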

Other observations

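Antibody genes were high in a library of sorted T cells, chosen for mention after the values were seen. Igkc, the immunoglobulin kappa constant gene, had 4151 scaled counts in the 10-month Foxp3Cre library and 688 in the library labelled Med23 KO, against 83.7 in LN, 85.1 in lean adipose and 240.1 in obese adipose. Jchain, which joins secreted antibodies, had 1103 in Foxp3Cre and 548 in the library labelled Med23 KO, 30.6 in lean and 93.8 in obese adipose, and was listed at 0 in LN. The Igkv segments summed to 2060 CPM in Foxp3Cre, 332 in the library labelled Med23 KO, 127 in obese adipose, 37.7 in lean adipose and 20.7 in LN. In Foxp3Cre 10 such segments were above 0, and the leading one, Igkv14-126, held 31.2% of the reads of all.

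Trav segments above 0 numbered 42 in Foxp3Cre and 10 in the library labelled Med23 KO, which had fewer reads, and 48 in LN, 26 in lean and 45 in obese adipose. Trbv segments numbered 19 in Foxp3Cre and 15 in the library labelled Med23 KO. The leading Trav segment, Trav7-4, held 30.6% of Trav reads in the library labelled Med23 KO and the leading one in Foxp3Cre, Trav21-dv12, 7.32%, while of Trbv reads the leading segment held 14.6% (Trbv13-1) and 28.0% (Trbv15), in the same order. Retnla, a gene of alternatively activated macrophages, had 722 in lean adipose, 654 in obese adipose, 10.4 in Foxp3Cre and 232 in the library labelled Med23 KO, and was listed at 0 in LN.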
